A study of Homo sapiens with 8 samples.

How the data were processed

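RNA was measured in 8 libraries of the human iPSC line 1231A3, 1 per group. Per the labels' protocols, iPSCs were kept on a laminin-511 E8 fragment. For the 3D protocol they were dissociated and aggregated in low-adhesion plates with 10 µM Y-27632, a ROCK inhibitor, then given 10 µM SB431542 and 10 ng/ml BMP4 from day 1, and SB431542 with 1 µM CHIR99021 from day 2 to day 5 on a shaker at 120 rpm. For the 2D protocol cells grew on laminin for 4 days and then received SB431542 and CHIR99021 for 10 days, with a change of medium every 2 days and no BMP4. CD271high cells were sorted from both. Total RNA, 10 ng per library, was amplified for 13 cycles with the Ion AmpliSeq transcriptome panel, which reads 1 amplicon per gene. The authors deposited raw counts per gene for each library, per the file headers, with no normalisation. Per the submitters' processing notes the build was hg19 and DESeq2 was used; the aligner and the counting tool are not given in the sources used here. The table names genes by symbol alone.

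The table held 20812 lines. Of these, 10 were ERCC spike-ins, with 0 counts in total, and were left out, which left 20802 genes. Of those, 28 had symbols turned into dates, with 0.206% to 0.296% of the counts of a library; they stayed in the totals and tests and were not named. Totals ran from 5661291 to 11712609 counts. A count of 3 corresponds, with the TMM factors, to 0.244 to 0.311 CPM in the 7 libraries other than 2D and to 0.514 CPM in the 2D library. From 15104 to 16376 genes had a count. Libraries were grouped by the labels. No library was left out of the tables; the 3D and 2D CD271high libraries were not part of the trend, which used the 6 unsorted ones.

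Size factors were TMM factors from all 8 libraries for pairs and from the 6 unsorted libraries for the trend. Genes with at least 20 counts in at least 1 of the 6 libraries were tested for a log-linear slope on day with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), which left 4 residual degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. With 1 library per day the model takes departures from a line as the spread, so a gene that peaks in between gets a large error. For 9 pairs of libraries, each day against the day before and the 4 comparisons of sorted cells, the log2 ratio of CPM with a pseudocount of 1 CPM was taken, and genes at 10 CPM or more in at least 1 of the pair were counted at 4-fold. Ratios of counts have exact Clopper-Pearson 95% intervals from the conditional binomial. The day of highest expression was counted over genes at 10 CPM in at least 1 of the 6 unsorted libraries with a range of at least 4-fold. Before the data were examined, 31 gene lists, the designs, the alternatives and the rule for named genes were fixed. The lists were pluripotency, neural plate border, neural crest specifiers, EMT and migration, epithelial junction, CNS neural progenitor, preplacodal, surface ectoderm, amnion and trophoblast, mesendoderm, targets of BMP, WNT, Nodal and TGF-beta, FGF and ERK, retinoic acid and Notch, midbrain and anterior axis, Schwann cell and glia, melanocyte, neuron, mesenchyme, smooth muscle and actomyosin, endothelium and blood, cell cycle, hypoxia and glycolysis, dissociation stress, p53 targets, unfolded protein response, cholesterol synthesis, laminin and integrin, and HOX genes. A list's median takes members at 1 CPM or more in at least 1 of the pair. Lists share some genes. The rule named the 10 highest and 10 lowest log2 ratios for the sort and for 3D against 2D, the 5 highest and 5 lowest for each step and for each comparison with iPSCs, the 10 highest and 10 lowest slopes past the threshold at 10 CPM, the 4 members of each list with the largest ratio or slope in size, and 25 key markers. From it 958 genes were set aside, which are sex-linked transcripts that say something of the donor and uncharacterised LOC symbols, besides the date symbols. The text names part of these genes.

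Transcript GC content came from GENCODE transcripts matched by symbol for 19686 genes (94.6%), and for 98.4% to 98.8% of genes at 10 CPM in each pair. It is that of whole transcripts, not of the amplicons. Other tools were limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The methods were tested on simulated data. For the trend, with 12667 genes, a dispersion of 0.02 and 200 changed genes, 86% of slopes of 0.25 and 100% of slopes of 0.5 log2 units per day were recovered, and 8 unchanged genes were called. For the pairs, 8-fold differences were recovered in 100% in each of the 9 comparisons with 0 unchanged genes called; the genes simulated numbered 9071, 8980, 8983, 8728, 8590, 8639, 9119, 9161 and 9526, in the order of steps, sort, 3D against 2D, 3D against iPSCs and 2D against iPSCs. Intervals held the true ratio in 94.9% to 95.5% of genes. These simulations hold counting noise and, for the trend, a set dispersion around an exact line. They do not show how often real genes, which depart from a line, are recovered. Alternatives were DESeq2 size factors, total counts, other filters and pseudocounts, counting intervals beyond 4-fold, DESeq2's Wald test, limma-trend, a quadratic term and leaving out each library of the trend in turn. Centring on GC content, thinning to the depth of the 2D library and leaving out genes steady in the other libraries were added after the data were seen.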

Results

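1231A3, a human induced pluripotent stem cell (iPSC) line, was induced towards neural crest, the migratory embryonic cell population that gives rise to peripheral neurons, glia, pigment cells and facial mesenchyme. Transcripts were counted with a targeted amplicon panel, in which a short PCR product stands for each gene. There were 8 libraries, 1 in each of 8 groups. They came from iPSCs before induction (day 0), from floating aggregates (3D) at days 1, 2, 3, 4 and 5, from cells of the 3D protocol sorted at day 5 for high CD271, and from cells sorted for high CD271 at day 10 of an adherent (2D) protocol. CD271 is the cell surface receptor encoded by NGFR and is used as a neural crest marker. The total was 11274603 counts at day 0, 11402779 at day 1, 11571491 at day 2, 10909986 at day 3, 10827053 at day 4 and 10935169 at day 5. It was 11712609 in the sorted 3D library and 5661291 in the sorted 2D library. The 2D library stood apart in other ways too. Its 100 most abundant transcripts held 34.8% of its counts, against 22.0% to 27.8% in the 7 other libraries. Spearman's rho of its levels with those of the other libraries, taken across genes, was 0.875 to 0.928, while rho between the sorted and unsorted day 5 libraries was 0.982. Its highest rho values were 0.928 and 0.926, with the unsorted and sorted day 5 libraries. Each of the 7 other libraries had a rho of 0.965 or more with its nearest library. The lowest rho within the 7 other libraries was 0.910, between iPSCs and sorted 3D cells. Genes are not independent replicates. No group had a replicate, so a difference between a pair of libraries has no p-value. Intervals and floors cover counting error only, as they come from the read counts of single libraries. PCR reads without molecular identifiers were counted, so the sampling of molecules is not fully covered either. Levels are normalised CPM, the counts of a gene scaled to a common library size, folds are ratios of CPM, and brackets after a fold hold its 95% counting interval. Genes are called 4-fold higher or lower after 1 CPM is added to both levels, which shrinks the ratios of scarce transcripts. Members of a gene list are higher or lower where they differ by at least 2-fold with a counting interval that excludes 1. A list's median is also given at bound, with members that had 0 counts in 1 library set to the ratio that 3 counts would give, where this differs.

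Which transcripts followed the days of induction was asked over the 6 unsorted libraries. Of 22 pluripotency genes 13 fell, and of 15 epithelial junction genes 12 fell, while 10 of 21 neural crest specifiers and 8 of 22 migration genes rose. POU5F1 (OCT4), a core pluripotency factor, fell by 1.77 log2 units per day (SE 0.18, adjusted p 0.00905), from 1420.4 CPM at day 0 to 7.27 CPM at day 5. NR2F2, a nuclear receptor of cranial neural crest, rose by 2.33 per day (SE 0.29, adjusted p 0.0130), from 0 to 79.8 CPM. CXCR4, a chemokine receptor that guides migrating cells, rose by 1.43 per day (SE 0.10, adjusted p 0.00498), from 2.11 to 218 CPM. The homeobox gene DLX2, a marker of cranial crest mesenchyme, rose by 2.08 per day (adjusted p 0.00778) to 35.4 CPM. SOX10, the transcription factor widely used to identify neural crest, went from 3.90 to 498 CPM and rose by 1.68 per day (SE 0.31, adjusted p 0.0247). Of 22 pluripotency genes tested, 0 rose and 13 fell over all genes (1 and 16 adjusted over the list alone). They include GDF3, which fell by 2.31 per day from 14.1 to 0 CPM, and TDGF1, the Nodal co-receptor, which fell by 3.31 per day. NANOG (202 and 5.61 CPM at days 0 and 5) and SOX2 (257 and 69.8 CPM) did not pass, with adjusted p of 0.0770 and 0.0693. Of 15 epithelial junction genes, 0 rose and 12 fell over all genes (0 and 14 adjusted over the list alone). EPCAM, an epithelial adhesion molecule, fell by 1.75 per day, from 377 to 1.29 CPM. The neural crest specifiers counted 21, of which 10 rose and 0 fell over all genes (13 and 1 adjusted over the list alone). TFAP2B, an AP-2 factor of neural crest, went from 0 to 506 CPM and NR2F1 from 0 to 408 CPM, both past the threshold. The sort marker NGFR (4.06 and 97.7 CPM) did not pass (slope 1.29, adjusted p 0.0623), nor did SNAI2 (0.0568), FOXD3 (0.325) and SOX9 (0.320). Of 22 genes of the epithelial to mesenchymal transition and migration, 8 rose and 0 fell over all genes (10 and 0 adjusted over the list alone). ZEB1, a repressor of epithelial genes, rose by 1.48 per day. Among the highest slopes was also PRSS56 (3.44), and among the lowest LCK (-2.70) and ZNF488 (-2.39). In the edgeR quasi-likelihood test of a log-linear trend with Benjamini-Hochberg adjustment, 576 of 13415 genes rose and 893 fell at an adjusted p of 0.05. DESeq2's Wald test called 1249 and 1719, and linear and quadratic terms tested together 1127 and 1710. The counts rest on single libraries: they were 36 and 153 without day 1, 332 and 691 without day 2, 53 and 90 without day 4, and 340 and 407 without day 5. POU5F1, NR2F2, CXCR4, DLX2, GDF3, LCK and ZNF488 passed whichever of the 6 libraries was left out. Each other call named here was lost on leaving out a library. The adjusted p was then 0.0861 without day 1, 0.0587 without day 4 and 0.0575 without day 5 for SOX10, 0.137 without day 0, 0.137 without day 1, 0.0659 without day 2 and 0.114 without day 4 for TFAP2B, 0.0559 without day 1, 0.0633 without day 4 and 0.0540 without day 5 for EPCAM and 0.0570 without day 1 and 0.0536 without day 4 for ZEB1. It was 0.0587 without day 1 for NR2F1, 0.0608 without day 4 for TDGF1 and 0.0712 without day 4 for PRSS56, which had too few counts for the test without day 5. A slope of a gene with 0 counts in some libraries depends on the prior count and is no bound.

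**Figure D1:**
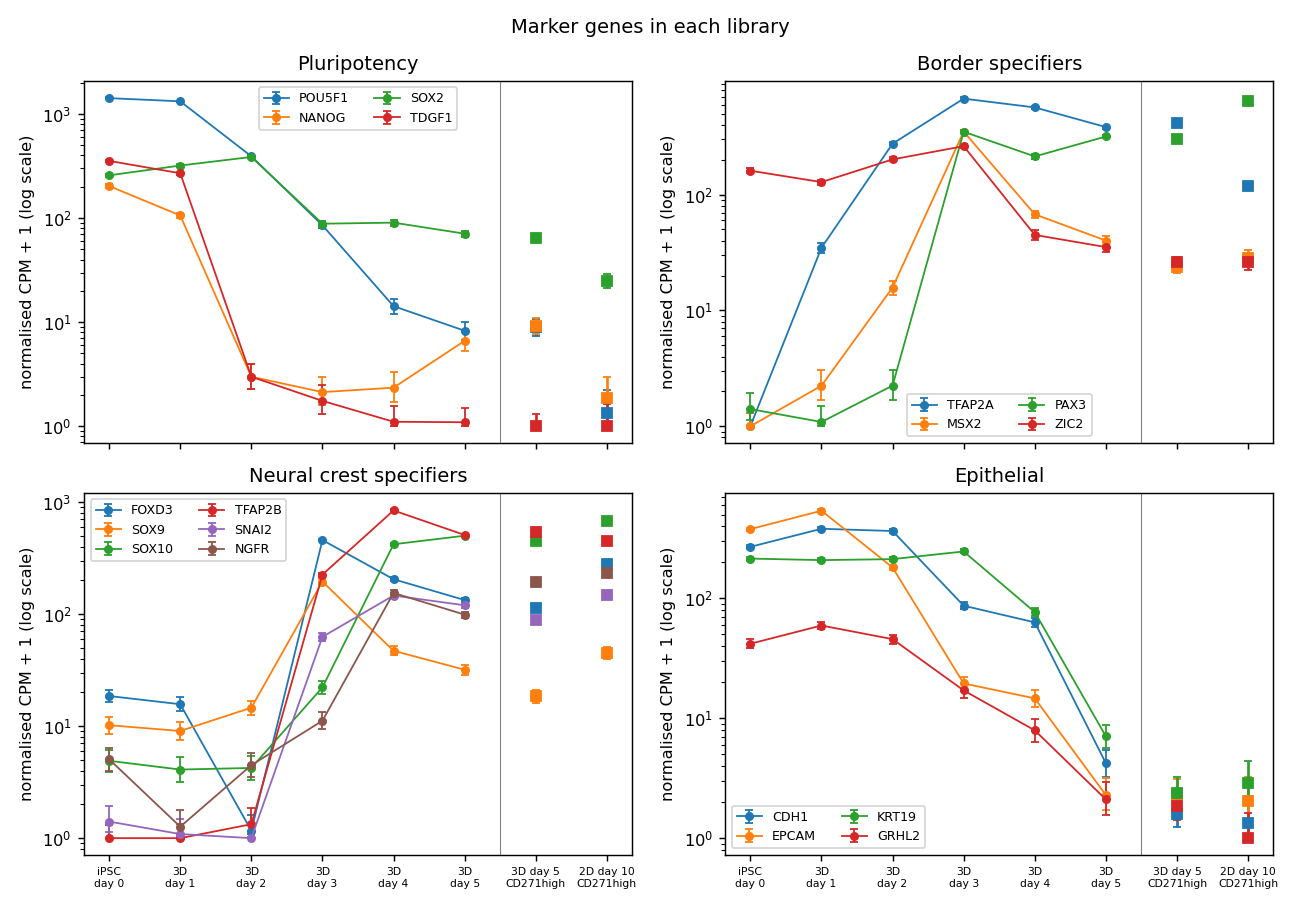
Levels of marker genes in each of the 8 libraries, as normalised CPM plus 1 on a log axis, in panels for pluripotency, border, neural crest and epithelial genes; lines join the 6 unsorted libraries, squares are the sorted libraries, and bars are 95% counting intervals of a single library. POU5F1 goes from 1420.4 CPM at day 0 to 7.27 CPM at day 5, while SOX10 goes from 3.90 to 498 CPM.

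The lists of other lineages and pathways were taken over the same days. The preplacodal genes, which mark the precursors of the sense organs, counted 10, of which 3 rose and 0 fell over all genes (4 and 1 adjusted over the list alone). EYA4, a placode gene, rose by 2.47 per day. Of 18 neuronal genes, 5 rose and 0 fell over all genes (8 and 1 adjusted over the list alone). The proneural factor NEUROD1 rose by 2.27 per day to 6.81 CPM and NEUROG1 by 2.26. Of 14 Schwann cell and glial genes, 4 rose and 1 fell over all genes (7 and 1 adjusted over the list alone). S100B, a calcium-binding protein gene of glia, rose by 1.74 per day. Mesenchyme genes numbered 18, of which 6 rose and 2 fell over all genes (9 and 3 adjusted over the list alone). DLX1 rose by 2.37 per day. Of 14 Nodal and TGF-beta targets, 1 rose and 5 fell over all genes (1 and 8 adjusted over the list alone). Of 15 FGF and ERK targets, 0 rose and 4 fell over all genes (0 and 6 adjusted over the list alone), among them ETV4, which fell by 1.60 per day from 113 to 0.736 CPM. Of 19 smooth muscle and actomyosin genes, 0 rose and 7 fell over all genes (1 and 7 adjusted over the list alone). CNN1, a calponin of smooth muscle, fell by 1.14 per day. The hypoxia and glycolysis list had 21 members tested, of which 0 rose and 4 fell over all genes (0 and 5 adjusted over the list alone). ADM, which encodes adrenomedullin, fell by 2.03 per day from 74.6 to 0 CPM, and VEGFA by 0.53. Of 23 laminin and integrin genes, 1 rose and 1 fell over all genes (2 and 6 adjusted over the list alone). LAMA4, a laminin chain gene, rose by 1.18 per day. Of 15 genes of the unfolded protein response, 0 rose and 3 fell over all genes (0 and 4 adjusted over the list alone). Of 18 p53 targets, 0 rose and 2 fell over all genes (0 and 3 adjusted over the list alone). For 18 neural plate border genes, 2 rose and 0 fell over all genes (2 and 0 adjusted over the list alone), ZIC1 being past the threshold with a slope of 1.20 (adjusted p 0.0145) while PAX3 (0.406 and 317 CPM) was not (adjusted p 0.0931). Among 17 BMP targets 2 rose and 0 fell over all genes (2 and 1 adjusted over the list alone), and among 17 WNT targets 1 rose and 1 fell over all genes (2 and 1 adjusted over the list alone). Among 12 retinoic acid targets 1 rose and 2 fell over all genes (2 and 2 adjusted over the list alone), and among 16 Notch targets 1 rose and 1 fell over all genes (1 and 1 adjusted over the list alone). Surface ectoderm had 11 members, of which 0 rose and 2 fell over all genes (0 and 2 adjusted over the list alone). For amnion and trophoblast, with 9 members, 1 rose and 0 fell over all genes (1 and 0 adjusted over the list alone), for mesendoderm, with 8, 1 rose and 0 fell over all genes (1 and 0 adjusted over the list alone), and for the midbrain and anterior axis, with 7, 1 rose and 0 fell over all genes (1 and 0 adjusted over the list alone). Of 22 cell cycle genes, 1 rose and 0 fell over all genes (1 and 0 adjusted over the list alone), the 1 being CCNE2 with a slope of 0.58. None of 17 neural progenitor genes of the central nervous system (CNS), 5 melanocyte, 4 endothelium and blood, 15 dissociation stress and 19 cholesterol synthesis genes passed in the edgeR test, over all genes or adjusted over the list alone. Of 38 HOX genes in the table, which give trunk cells their axial position, 0 reached 10 CPM in any library, the highest being HOXA3 with 0.265 CPM in the day 1 library. ETV4 and ADM passed whichever library was left out, and NEUROD1 passed without each of days 0 to 4 and had too few counts for the test without day 5. The other calls named here did not, with an adjusted p of 0.0548 without day 0 and 0.0697 without day 1 for EYA4, 0.0686 without day 0, 0.0999 without day 1 and 0.0535 without day 2 for S100B, 0.0782 without day 4 and 0.0685 without day 5 for CNN1 and 0.0605 without day 0 and 0.0587 without day 4 for VEGFA. It was 0.0605 without day 1 and 0.0598 without day 4 for ZIC1 and 0.0634 without day 1, 0.0623 without day 4 and 0.0588 without day 5 for CCNE2. It was 0.0569 without day 1 for NEUROG1, 0.0570 without day 1 for DLX1 and 0.0558 without day 1 for LAMA4.

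Each day was then compared with the day before, to see when each group of genes moved. Genes peaked at each of the days: of 2064 genes that spanned at least 4-fold over days 0 to 5, among 10285 at 10 CPM or more, 591 were highest at day 0, 325 at day 1, 291 at day 2, 305 at day 3, 232 at day 4 and 320 at day 5. In the library of day 1, after transfer to aggregates, targets of FGF signalling were lower than in iPSCs and BMP targets were higher. DUSP6, a phosphatase induced by ERK, was at 301 CPM at day 0 and 22.9 CPM at day 1, 13.1-fold (11.6 to 15.0) lower, and ETV4 was at 113 and 18.7 CPM. ID1, a direct BMP target, went the other way, from 39.9 to 323 CPM, 8.10-fold (7.37 to 8.92) higher. TFAP2A, a factor of the non-neural ectoderm and neural crest, had 0 counts at day 0 and 33.8 CPM at day 1, at least 139-fold higher. POU5F1 was at 1420.4 and 1324 CPM and NANOG at 202 and 105 CPM. For FGF and ERK targets the median log2 ratio was -1.63 (-1.80 at bound), with 0 higher, 12 lower and 4 neither among 16 members. For BMP targets it was 1.21 (2.24 at bound), with 8 higher, 0 lower and 3 neither among 11. Neural plate border genes had a median of 1.10 (1.33 at bound) over 11 members, while hypoxia and glycolysis genes had -0.81 over 21 and laminin and integrin genes -0.85 over 23. Pluripotency genes had 0.08, and 3 of 22 members were higher, 1 was lower and 18 were neither. Other transcripts with large ratios were OLIG3 (0.569 to 34.8 CPM), SERPINB9 (28.3 to 574 CPM) and SLC16A3 (18.4 to 1.24 CPM). Of 9270 genes at 10 CPM or more in either library, 72 were at least 4-fold higher and 43 at least 4-fold lower at day 1. Scaled by total counts alone, 62 were higher and 62 lower, and the median log2 ratio of all genes shifts by -0.13. The ratios had a Spearman's rho of -0.30 with transcript GC content across genes. The labels do not say whether a day's cells were taken before or after that day's change of medium.

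At day 2, after a day in BMP4 with the TGF-beta receptor inhibitor SB431542, Nodal pathway and pluripotency genes were lower and border genes higher than at day 1. NANOG was at 105 CPM at day 1 and 1.99 CPM at day 2, 52.8-fold (35.3 to 82.7) lower, and TDGF1 went from 269 to 1.99 CPM, 135-fold (90.7 to 211) lower. POU5F1 was at 1324 and then 391 CPM. The border genes PRDM1 and TFAP2A went from 0.177 to 63.4 CPM and from 33.8 to 274 CPM. DMBX1, a homeobox gene of the midbrain, was at 1.41 CPM and then 149 CPM, and LMO1 and PRTG were also among the highest ratios, with 161 and 337 CPM at day 2. FOXD3, which is expressed in both pluripotent cells and neural crest, was at 14.7 CPM and then at 0.166 CPM (2 counts), 88.5-fold (24.1 to 737) lower. The median log2 ratio was 1.52 for 15 border genes, with 11 higher, 0 lower and 4 neither, and 3.07 for 5 genes of the midbrain and anterior axis, with 4 higher, 0 lower and 1 neither. For pluripotency it was -0.996 (0 higher, 11 lower and 11 neither among 22) and for Nodal and TGF-beta targets -1.26 (0 higher, 7 lower and 6 neither among 13). CNS progenitor genes had a median of 1.30, and 7 of 12 members were higher, 2 were lower and 3 were neither. Of 9204 genes, 87 were at least 4-fold higher and 68 at least 4-fold lower at day 2.

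At day 3, a day after the WNT agonist CHIR99021 was first given with SB431542, neural crest and WNT genes were higher and epithelial genes lower than at day 2. FOXD3 was at 0.166 CPM at day 2 (2 counts) and 455 CPM at day 3, 2749-fold (761 to 22704) higher. PAX3 went from 1.24 to 348 CPM, TFAP2B from 0.331 to 224 CPM and SOX9 from 13.6 to 194 CPM. SNAI2, a repressor of E-cadherin, had 0 counts and then 61.6 CPM, at least 248-fold higher. AXIN2, a feedback target of WNT signalling, was 5.26-fold (4.65 to 5.95) higher, at 138 CPM. The epithelial adhesion genes CDH1 (E-cadherin) and EPCAM went from 364 to 85.9 CPM and from 180.3 to 18.5 CPM. CYP26A1, which degrades retinoic acid, was at 181 and then 1.88 CPM, HES3 at 232 and then 3.95 CPM, and SOX2 at 386 and then 87.3 CPM. Among neural crest specifiers the median log2 ratio was 1.97, and 12 of 18 members were higher, 0 were lower and 6 were neither. For genes of the epithelial to mesenchymal transition and migration it was 1.33 (13 higher, 1 lower and 8 neither among 22), for WNT targets 1.21 (9 higher, 1 lower and 6 neither among 16) and for epithelial junction genes -1.47 (0 higher, 12 lower and 3 neither among 15). Genes of other fates were also higher. CNS progenitor genes had a median of 1.76 (2.30 at bound) over 17 members and amnion and trophoblast genes 3.03 (3.53 at bound) over 8. Of 9295 genes, 172 were at least 4-fold higher and 105 at least 4-fold lower at day 3.

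At day 4 most neural crest specifiers were higher than at day 3 and some were lower, while most border, CNS and midbrain genes were lower. SOX10 was at 21.2 CPM at day 3 and 418 CPM at day 4, 19.8-fold (17.3 to 22.7) higher, and NGFR went from 10.2 to 153 CPM, 15.1-fold (12.4 to 18.5) higher. The glial gene S100B went from 6.02 to 199.8 CPM, and ITGA4, an integrin subunit of migrating crest, from 3.67 to 303 CPM. NR2F1 was at 22.1 and then 371 CPM. In contrast, FOXD3 went from 455 to 203 CPM, SOX9 from 194 to 46.0 CPM and PAX3 from 348 to 213 CPM. The border gene MSX2 was at 349 CPM and then 66.6 CPM, LHX5, a homeobox gene of the forebrain, at 186 and then 6.11 CPM, and DLK1 at 513 and then 22.3 CPM. LRAT, which makes retinyl esters, was 56.9-fold (40.8 to 81.9) lower. Neural crest specifiers had a median log2 ratio of 1.84, and 15 of 21 members were higher, 4 were lower and 2 were neither. Schwann cell and glial genes had 0.91 (7 higher, 2 lower and 5 neither among 14) and mesenchyme genes 0.94 (9 higher, 2 lower and 8 neither among 19), among them COL1A2 from 90.2 to 857 CPM. The median was -1.52 for 16 border genes, of which 11 were lower and 1 higher. It was -1.67 (-1.92 at bound) for 16 CNS progenitor genes and -1.21 (-1.85 at bound) for 10 genes of the midbrain and anterior axis. Of 9184 genes, 129 were at least 4-fold higher and 208 at least 4-fold lower at day 4; scaling by total counts alone shifts the median of all genes by -0.12.

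At day 5 fewer genes differed from the day before. Cholesterol synthesis and neuronal genes were higher and epithelial genes lower. HMGCS1, an early enzyme of sterol synthesis, went from 90.5 to 351 CPM between day 4 and day 5. STMN2 and NEFM, genes of growing neurites and neurofilaments, went from 9.01 to 39.0 CPM and from 10.5 to 52.4 CPM. CDH1 was at 62.1 CPM and then 3.22 CPM, 19.3-fold (13.7 to 28.0) lower, and KRT19, a simple epithelial keratin, at 75.9 and then 6.07 CPM. ITGB1, the integrin subunit shared by most laminin receptors, was 11.5-fold (10.3 to 13.0) lower, at 30.9 CPM. The immediate early gene EGR1 went from 6.31 to 63.7 CPM and the protease gene ECEL1 from 12.0 to 180.3 CPM. The median log2 ratio of cholesterol synthesis genes was 1.69, and 13 of 19 members were higher, 0 were lower and 6 were neither. For neuronal genes it was 1.20 (9 higher, 0 lower and 8 neither among 17), for epithelial junction genes -1.95 (0 higher, 11 lower and 3 neither among 14) and for surface ectoderm genes -1.37 (0 higher, 9 lower and 3 neither among 12). Neural crest specifiers had -0.05, and 0 of 21 members were higher, 1 was lower and 20 were neither. Of 8953 genes, 13 were at least 4-fold higher and 60 at least 4-fold lower at day 5. Scaled by total counts alone, which shifts the median of all genes by 0.15, 20 were higher and 43 lower.

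**Figure D2:**
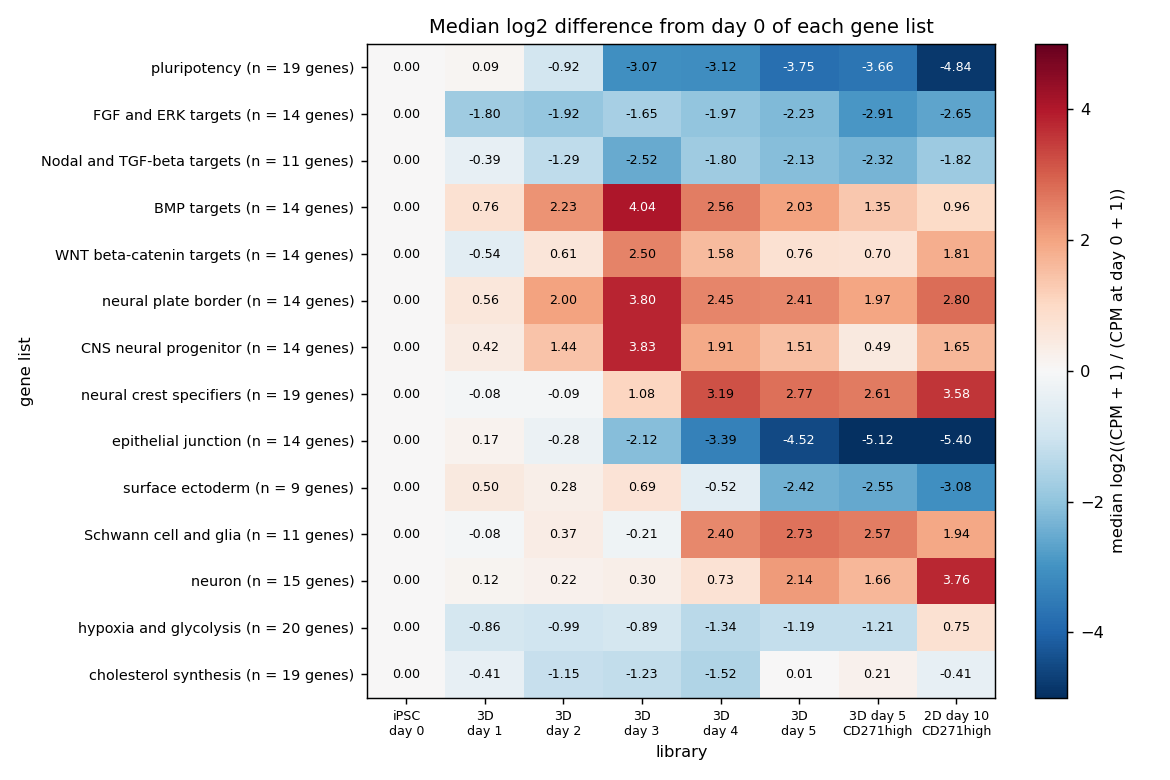
Median log2 difference from the day 0 library of each gene list (vertical axis, with its number of genes) in each library (horizontal axis), coloured from blue (lower) to red (higher) and printed in each square. Border genes are highest at day 3 with 3.80, neural crest specifiers among the 3D libraries at day 4 with 3.19, and epithelial junction genes reach -4.52 at day 5.

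The sorted CD271high cells of day 5 were compared with unsorted cells of the same day, to see which transcripts the gate enriched. The libraries were close to each other. NGFR itself, which checks the sort, was at 97.7 CPM in unsorted and 190.3 CPM in CD271high cells, 1.95-fold (1.81 to 2.10) higher. The neural crest genes SOX10 (498 unsorted, 451 sorted), FOXD3 (132 and 113), PAX3 (317 and 301) and TFAP2B (506 and 536 CPM) differed by less than 2-fold. TBX3, a T-box factor, was at 11.3 CPM in unsorted and 1.89 CPM in sorted cells, 5.98-fold (3.78 to 9.89) lower. ZIC1, a border and neural gene, was 4.65-fold (3.24 to 6.85) lower, the neuronal gene STMN2 3.94-fold (3.20 to 4.89) lower and HAPLN1, a hyaluronan link protein, 2.93-fold (2.51 to 3.43) lower. Also among the lowest were the lens and placode gene FOXE3 (10.6 and 2.41 CPM), the netrin receptor gene DCC (12.5 and 3.96) and the Notch ligand gene DLL3 (22.4 and 8.09). The highest ratios were 4.46-fold (2.99 to 6.85) for MECR, 2.14-fold (1.73 to 2.66) for the immediate early gene FOS and 2.26-fold (2.08 to 2.45) for the cystine transporter gene SLC7A11, with 172 CPM after sorting. None of 21 neural crest specifiers was 2-fold higher or lower, and their median log2 ratio was -0.11. Lists of other fates did not move alike. CNS progenitor genes had a median of -0.72 (0 higher, 5 lower and 8 neither among 13), neuronal genes -0.76 (0 higher, 4 lower and 13 neither among 17), surface ectoderm genes -0.78 (0 higher, 4 lower and 6 neither among 10), amnion and trophoblast genes -0.84 (0 higher, 2 lower and 3 neither among 5) and epithelial junction genes -0.51 (0 higher, 3 lower and 5 neither among 8). The median was -0.28 for mesenchyme, -0.16 for endothelium and blood, -0.15 for Schwann cell and glial genes and -0.03 for preplacodal genes, and it was 0.01 for midbrain and anterior axis, 0.09 for smooth muscle and actomyosin, 0.17 for mesendoderm and 0.29 for melanocyte genes. Dissociation stress genes had a median of 0.17 over 14 members. Of 8770 genes, 0 were at least 4-fold higher in sorted cells and 1, TBX3, was at least 4-fold lower, with 1 CPM added to both levels. TBX3 dropped below 4-fold with a pseudocount of 5 CPM.

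CD271high cells of the 3D protocol were compared with iPSCs to describe the product against its starting point. Most neural crest genes were higher and pluripotency and epithelial genes far lower. CDH6, a cadherin of neural crest, was at 1.87 CPM in iPSCs and 1667 CPM in sorted 3D cells, 892-fold (595 to 1408) higher. TFAP2B, TFAP2A and NR2F1 had 0 counts in iPSCs and 536, 411 and 379 CPM in sorted cells, which is at least 2198-fold, at least 1687-fold and at least 1555-fold higher. SOX10 was 116-fold (87.1 to 157) higher and NGFR 46.9-fold (35.4 to 63.3) higher. PODXL, a sialomucin of pluripotent cells, went from 1272 to 1.98 CPM, 643-fold (428 to 1014) lower, and ESRG, a non-coding RNA of pluripotent cells, from 579.6 to 0.602 CPM. TDGF1 was at 354 CPM in iPSCs and had 0 counts in sorted cells, at least 1370.3-fold lower, and POU5F1 was at 7.91 CPM, 179-fold (146 to 223) lower. Neural crest specifiers had a median log2 ratio of 2.58 (3.30 at bound), and 16 of 20 members were higher, 1 was lower and 3 were neither. The lower member was ETS1, with a log2 ratio of -3.49. For border genes it was 1.97 (2.16 at bound, 10 higher, 3 lower and 3 neither among 16), for Schwann cell and glial genes 2.04 (2.33 at bound, 10 higher, 3 lower and 1 neither among 14) and for neuronal genes 1.66 (1.77 at bound, 11 higher, 4 lower and 0 neither among 15). Pluripotency genes had -3.55 (-3.66 at bound), and 1 of 21 members was higher, 19 were lower and 1 was neither. Epithelial junction genes had -4.71 (-5.54 at bound) and all 15 were lower. Hypoxia and glycolysis genes had a median of -1.20 (0 higher, 13 lower and 8 neither among 21) and FGF and ERK targets -2.61 (2 higher, 11 lower and 3 neither among 16). Of 9666 genes, 332 were at least 4-fold higher and 745 at least 4-fold lower in sorted 3D cells. Scaling by total counts alone shifts the median of all genes by -0.13, and the ratio had a Spearman's rho of -0.27 with transcript GC content across genes.

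The same comparison with iPSCs was made for CD271high cells of the 2D protocol, with the same iPSC library, so a likeness of both lists is not read as a shared effect. PAX3 was at 0.406 CPM in iPSCs and 642 CPM in sorted 2D cells, 1580.3-fold (677 to 4870.0) higher. NR2F2, NR2F1 and TFAP2B had 0 counts in iPSCs and 613, 508 and 446 CPM in 2D cells, which is at least 2514-fold, at least 2085-fold and at least 1831-fold higher. POU5F1 was at 0.343 CPM (2 counts), 4145-fold (1147 to 34229) lower, and ESRG had 0 counts, at least 1128-fold lower by counting alone. DNMT3B, the de novo DNA methyltransferase of pluripotent cells, was at 338 CPM in iPSCs and 0.171 CPM (1 count) in 2D cells, 1972-fold (354 to 77894) lower. Loss of amplicons in the 2D library stays open, so these low counts set no bound on the transcripts in the cells. Neural crest specifiers had a median log2 ratio of 3.01 (3.91 at bound), and 18 of 21 members were higher, 1 was lower and 2 were neither. The lower member was again ETS1, with a log2 ratio of -4.57. Neuronal genes had 2.89 (14 higher, 2 lower and 3 neither among 19), border genes 2.61 (2.82 at bound, 10 higher, 4 lower and 2 neither among 16) and Notch targets 1.59 (9 higher, 2 lower and 4 neither among 15). Pluripotency genes had -4.60 (-4.78 at bound), with 0 higher, 19 lower and 2 neither among 21, and all 15 epithelial junction genes were lower, with a median of -5.39 (-5.43 at bound). Cell cycle genes had a median of -1.14 (0 higher, 12 lower and 10 neither among 22), dissociation stress genes 1.07 (8 higher, 2 lower and 5 neither among 15) and hypoxia and glycolysis genes 0.89 (10 higher, 4 lower and 7 neither among 21). CNS progenitor genes had 1.27 (1.94 at bound) over 17 members and melanocyte genes 1.58 over 7; the signs of both turn when only members at 10 CPM are taken, to -2.88 and -0.69. Of 10028 genes, 668 were at least 4-fold higher and 1114 at least 4-fold lower in 2D cells. The ratio had a Spearman's rho of 0.295 with transcript GC content across genes. After centring on GC content, 684 were at least 4-fold higher and 862 at least 4-fold lower. The centred list medians were 3.16 for neural crest specifiers, 3.19 for neuronal genes, 2.15 for border genes and 1.07 for Notch targets. They were -3.80 for pluripotency, -5.41 for epithelial junction, 0.77 for hypoxia and glycolysis, 0.94 for CNS progenitor and 1.45 for melanocyte genes. For cell cycle and dissociation stress genes they were -0.88 and 0.90, both below 1 in size.

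CD271high cells of both protocols were compared directly, to see how the 3D product at day 5 differs from the 2D product at day 10. Neural crest markers were present in both. NGFR was at 190.3 CPM in 3D and 234 CPM in 2D cells, SOX10 at 451 and 668, PAX3 at 301 and 642, and FOXD3 at 113 and 279 CPM. TFAP2A was 3.52-fold (3.25 to 3.82) higher and CDH6 2.51-fold (2.43 to 2.60) higher in the 3D library. SST, which encodes the neuropeptide somatostatin, was at 96.5 CPM in 2D and 0.0860 CPM (1 count) in 3D, 1121-fold (200.4 to 44368) lower, and the sensory neuron factors POU4F1 and NEUROD1 were at 66.0 and 48.8 CPM in 2D against 6.71 and 3.61 in 3D. NR2F2 was 7.89-fold (7.33 to 8.49) lower in 3D and COL1A1, the alpha-1 chain of type I collagen, 34.1-fold (27.5 to 42.8) lower. The lactate exporter gene SLC16A3 was at 101 CPM in 2D and 0.0860 CPM (1 count) in 3D, and the glycolysis gene ALDOC at 108 and 3.27 CPM. IGFBP3 was 52.6-fold (32.5 to 91.1) lower in 3D. The highest ratios in the 3D library belonged to RMND5A (167 CPM against 1 count), RRP7A (96.7 CPM against 1 count) and PSMG1, at 82.1-fold (54.6 to 129.6). Also among them were the kinesin gene CENPE, at 82.5-fold (41.8 to 192), and NFYC, at least 109-fold higher by counting alone. Of the 10 highest, 3 were steady within 2-fold over the 7 libraries other than 2D. Neuronal genes had a median log2 ratio of -1.87 (-2.01 at bound), and 0 of 18 members were higher, 14 were lower and 4 were neither. For hypoxia and glycolysis genes it was -1.14 (-2.02 at bound, 0 higher, 14 lower and 7 neither among 21), for Notch targets -1.13 (1 higher, 8 lower and 6 neither among 15) and for cell cycle genes 1.18 (12 higher, 0 lower and 10 neither among 22). It was -1.92 (0 higher, 5 lower and 0 neither among 5) for amnion and trophoblast genes, -1.26 (1 higher, 4 lower and 2 neither among 7) for melanocyte genes, -1.21 (-1.29 at bound, 1 higher, 10 lower and 6 neither among 17) for smooth muscle and actomyosin genes, -1.02 (2 higher, 8 lower and 5 neither among 15) for CNS progenitor genes and 0.81 (8 higher, 1 lower and 8 neither among 17) for pluripotency genes. Neural crest specifiers had -0.29 (2 higher, 6 lower and 13 neither among 21). The ratio of the 3D to the 2D library followed transcript GC content, with a Spearman's rho of -0.553 across genes and medians of 0.95 in the quartile of genes lowest in GC and -0.73 in the highest. After the median of each of 20 GC bins was set to 0, the medians were -1.55 for neuronal genes, -1.44 for hypoxia and glycolysis genes, 0.92 for cell cycle genes, -0.21 for Notch targets, -1.60 for amnion and trophoblast genes, -0.94 for melanocyte genes, -0.72 for smooth muscle and actomyosin genes, -0.41 for CNS progenitor genes, 0.59 for pluripotency genes and 0.28 for neural crest specifiers, the last with the sign turned. For single genes, the log2 ratio was -4.92 before and -4.01 after for COL1A1, -6.49 and -6.16 for SST, -2.96 and -3.13 for NR2F2, 1.81 and 2.13 for TFAP2A, and 5.59 and 4.47 for CENPE. Centred log2 ratios to iPSCs in 3D and 2D were 5.65 and 5.02 for NGFR and 7.05 and 6.69 for SOX10, which turned their order. They were 7.87 and 8.71 for PAX3 and 3.13 and 3.51 for FOXD3, which stayed higher in 2D. Of 9601 genes, 775 were at least 4-fold higher and 465 at least 4-fold lower in the 3D library. After the GC bins were centred the counts were 340 and 350.

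**Figure D3:**
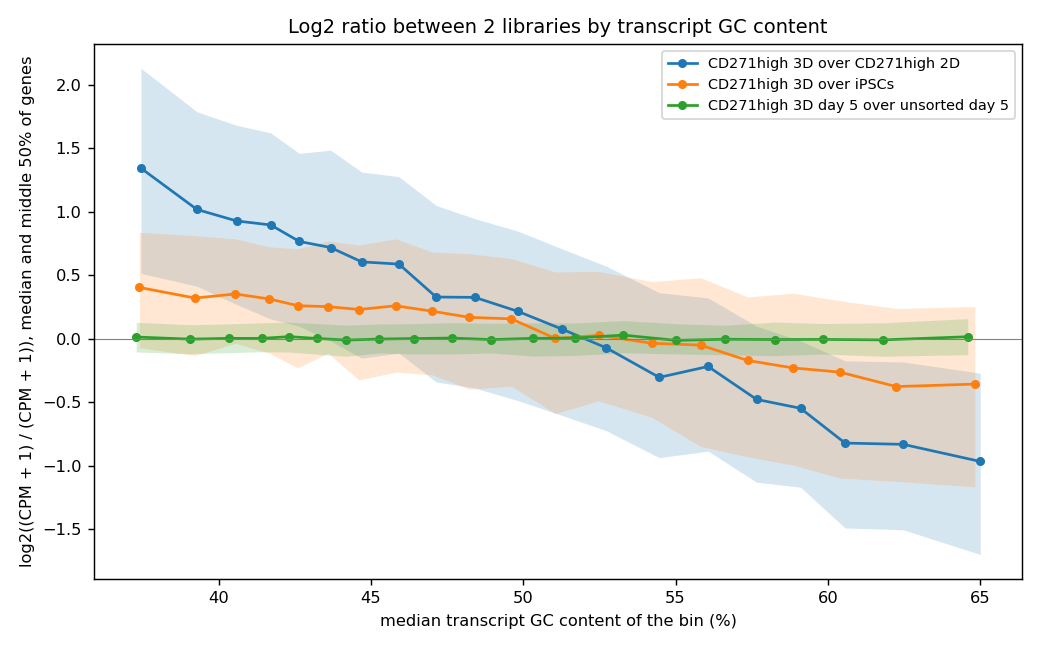
Log2 ratio of the CPM of a pair of libraries (vertical axis) against the median transcript GC content in percent of 20 bins of genes (horizontal axis); points are medians of the genes in a bin and bands hold the middle 50% of them. The ratio of sorted 3D to sorted 2D cells goes from 1.34 in the bin lowest in GC to -0.97 in the highest, and that of sorted to unsorted day 5 cells stays between -0.01 and 0.03.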

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

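Of the tests in this part, GC centring was added as an alternative after the data were seen. The results here drew attention because CD271high cells of the 3D protocol lay on one side of the iPSC library and those of the 2D protocol on the other. These differences between protocols were not tested, as each group is a single library. The median log2 ratio to iPSCs of hypoxia and glycolysis genes was -1.20 in 3D and 0.89 in 2D cells. For the cyclin gene CCNE2 it was 2.47 in 3D and -1.09 in 2D. COL1A1, the alpha-1 chain of type I collagen, had -3.54 in 3D and 1.37 in 2D. IGFBP3 had -2.45 in 3D and 2.54 in 2D. For KIT, a receptor of melanocyte precursors, the values were 1.14 and -1.14, and for the glycosyltransferase gene MFNG, which acts on Notch, they were -2.46 and 2.13. When GC bins were centred, the values in 3D and 2D became -1.46 and 0.77 for the hypoxia and glycolysis median, 2.15 and -0.43 for CCNE2, -3.07 and 1.05 for COL1A1, -2.33 and 2.40 for IGFBP3, 0.88 and -0.74 for KIT and -1.99 and 1.80 for MFNG. KIT was then less than 2-fold from the iPSCs in both and CCNE2 in 2D.

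The hypoxia and glycolysis genes were weighed further. VEGFA was at 93.7 CPM in sorted 2D and 5.08 CPM in sorted 3D cells, and ALDOC at 108 and 3.27 CPM. The list was split against iPSCs. The log2 ratio in 3D and 2D was -6.24 and -5.10 for ADM, -3.91 and -2.81 for SLC2A3 and -2.94 and -2.62 for SLC2A1, lower in both. It was -3.78 and 0.89 for ALDOC and -0.18 and 2.43 for PFKFB4. Loss of transcripts of low GC content in the 2D library is argued against, since the list's median log2 ratio of 3D to 2D was -1.14 and became -1.44 when GC bins were centred. Adherent culture against aggregates stays open and was not tested, since the only other adherent library is that of the iPSCs, which the comparison already rests on. Time in culture, BMP4 and the library preparation of the 2D cells differ together with the protocol and were not tested, nor was any other biological difference.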

How the results depend on the processing

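Centring on GC content, thinning and leaving out genes steady in the other libraries were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers and 1 library per group. Depth limits the 2D library, where 3 counts equal 0.514 CPM, so by counting alone a transcript absent there lies below about that level. Loss of amplicons or GC-dependent loss in that library stays open, so absence there sets no bound on the transcript in the cells. NFYC, with a mean of 50.4 CPM in the 7 other libraries, had 0 counts there. Chance order of the days is argued against as the source of the trend count: the real order gave 1469 genes, the most of 100 orders. The next order, with days 0 and 1 exchanged, gave 948, so no other order drawn was as large. Libraries of neighbouring days were alike, so most other orders could not give a line, and 95 of those drawn gave 0 genes. The test therefore shows only that levels followed the days, not which calls hold or why. The trend counts depend on the model and on single libraries. DESeq2's Wald test gave 1249 genes that rose and 1719 that fell, and linear and quadratic terms together gave 1127 and 1710, where the second term also takes genes that peak in between. Leaving out 1 library in turn gave 36 to 504 genes that rose and 90 to 883 that fell. The other scalings, filters and limma-trend gave 428 to 680 and 898 to 1134.

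A pseudocount of 5 CPM shrinks ratios by construction. With it the genes higher and lower were 34 and 18 at day 1, 41 and 30 at day 2, 91 and 43 at day 3, 74 and 88 at day 4, and 4 and 20 at day 5. For 3D against 2D they were 491 and 200, for 3D against iPSCs 202 and 423, and for 2D against iPSCs 382 and 688. The days of highest expression then held 312, 208, 152, 197, 151 and 183 genes for days 0 to 5. A filter at 50 CPM leaves fewer genes. It gave 22 and 18 at day 1, 40 and 27 at day 2, 69 and 39 at day 3, 52 and 72 at day 4, and 5 and 22 at day 5, then 485 and 153 for 3D against 2D, 157 and 248 for 3D against iPSCs and 296 and 535 for 2D against iPSCs. The days of highest expression held 202, 126, 101, 122, 116 and 130 genes. At day 5, total counts gave 20 genes higher and a pseudocount of 0.1 CPM gave 21; total counts also gave 147 genes highest at day 4. For the sort, a pseudocount of 0.1 CPM gave 1 higher and 3 lower and no filter gave 2 lower, while a pseudocount of 5 CPM, a filter at 50 CPM and intervals beyond 4-fold gave 0 lower. GC centring gave 340 genes higher for 3D against 2D. Where the construction does not show it, the cause was not tested.

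Of list medians of at least 1 in size, the direction turned for 2, both for 2D against iPSCs with members at 10 CPM, which leaves fewer genes: -2.88 in place of 1.27 for CNS neural progenitors and -0.69 in place of 1.58 for melanocytes. For smaller medians the sign turned 74 times over all alternatives, 11 of them with GC centring, among them, for 3D against 2D, border genes from -0.41 to 0.44, neural crest specifiers from -0.29 to 0.28 and retinoic acid targets from -0.37 to 0.04. Apart from the 2, list medians moved beyond their interval 424 times and did not 1434 times. Among alternatives for single genes in pairs, 1836 moved and 4350 did not. For the trend, its counts included, 1571 stayed the same, 138 were stronger and 176 weaker. A gene of the trend was the same where it kept its side of the threshold. A count of the trend was the same where it stayed within 1.5 times. Of the counts in pairs and by day, 120 stayed within 1.5 times and 54 did not. Thinning gave 773 and 469 for 3D against 2D and 676 and 1109 for 2D against iPSCs. Without genes steady in the other libraries the counts for 3D against 2D were 530 and 461.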

Other observations

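Cholesterol synthesis genes had a course of their own. Relative to day 0, the median log2 level of 19 members was -0.41 at day 1, -1.15 at day 2, -1.23 at day 3, -1.52 at day 4 and 0.01 at day 5. HMGCS1 was at 316 CPM at day 0, 90.5 CPM at day 4 and 351 CPM at day 5.

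Day 3 also held a short peak of some genes from other lineages, which were picked for this course after their values were seen. The developmental regulators HAND1 and CDX2, which mark amnion, trophoblast and mesoderm, were at 37.1 and 12.6 CPM at day 3, at 2.73 and 0 CPM at day 2 and at 2.17 and 1.86 CPM at day 4. The secreted BMP regulator BMPER was at 20.05, 308 and 13.4 CPM at days 2, 3 and 4, the WNT antagonist DKK1 at 1.99, 25.8 and 2.28 CPM, and LMX1A, a factor of the dorsal midline, at 8.62, 56.1 and 8.59 CPM. Relative to day 0, the median log2 level at days 2, 3 and 4 was 1.01, 3.85 and 1.59 for amnion and trophoblast genes and 3.19, 5.09 and 1.67 for midbrain and anterior axis genes. It was also highest at day 3 for CNS progenitors (1.44, 3.83 and 1.91), BMP targets (2.23, 4.04 and 2.56), border genes (2.00, 3.80 and 2.45), WNT targets (0.61, 2.496 and 1.58), migration genes (0.33, 2.01 and 1.51), preplacodal genes (0.575, 2.25 and 1.77), surface ectoderm genes (0.28, 0.69 and -0.52) and dissociation stress genes (-0.54, 0.28 and -0.10). It was not for neuronal (0.22, 0.30 and 0.73), mesenchyme (0.08, 0.31 and 1.28), Schwann cell and glial (0.37, -0.21 and 2.40) and melanocyte genes (0.19, 0.13 and -0.25). Not every list highest at day 3 had a short peak. At day 5 the median was 2.28 for midbrain and anterior axis, 2.17 for preplacodal, 2.41 for border and 1.48 for migration genes. For amnion and trophoblast, CNS progenitor, BMP target, WNT target, surface ectoderm and dissociation stress genes it was 0.91, 1.51, 2.03, 0.76, -2.42 and 0.12. GATA3, of the surface ectoderm and BMP target lists, was at 10.9, 1.98 and 8.80 CPM at days 2, 3 and 4, lowest of these at day 3.

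In what follows, the tests of depth by thinning, of amplicon loss by direction, of GC content by centring and of cells outside the gate were chosen after the results were seen. Of 2244 genes steady within 2-fold over the 7 other libraries, 62 were at least 8-fold lower in the 2D library. Each other library had 0, but its genes had to be steady in 2D too, which left 1074 to 1239. With 2D left out of that choice there were 2307 to 2724 genes, and 0 were 8-fold lower in each other library. The 2D library alone came from another protocol and day, so the comparison is not between like libraries. BTF3 and HNRNPM, chosen after their values were seen, had means of 1468.5 and 904 CPM in the other libraries and 69.2 and 94.8 CPM in 2D. Lower depth of the 2D library is argued against: with each of the 7 other libraries thinned to the 2D total, 0 of the genes steady in the 6 libraries left were at least 8-fold lower in the thinned one, against 62 or more in 2D on the same genes. GC-dependent loss stays open: the ratio of the 2D library to the others followed transcript GC content across steady genes with a Spearman's rho of 0.494, and with GC bins centred the median log2 ratio of 3D to 2D over the 62 genes went from 3.37 to 2.60, those at 8-fold or more from 51 to 13, and 53 stayed at 4-fold or more. Loss of amplicons in the 2D library's preparation or panel lot, which takes genes one way only, stays open too, as 0 steady genes were at least 8-fold higher in 2D, and so does a true difference of the 2D cells, which was not tested; of the 775 genes higher in 3D than in 2D, 245 were steady in the others.

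Sorted and unsorted day 5 cells differed little. That a single library stands under both names is excluded, since counts differed with a chi-square of 6.92 per degree of freedom over 12313 genes, far beyond counting noise. That the cells outside the gate lacked neural crest expression is argued against too: specifiers confined to the gated cells would be enriched about as much as NGFR, with a log2 ratio of 0.95, but the median of 20 specifiers other than NGFR was -0.13. NGFR encodes the sorted marker, and its enrichment is that of 1 gene in 1 pair of libraries, so it does not settle how many cells the gate held. A gate that held nearly all cells would also leave the specifiers unchanged. The argument therefore holds only where the gate left out many cells, and their share is not in the labels. A shared neural crest character on both sides of the gate stays open, and how pure the sort was, was not tested.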
